A study of Homo sapiens with 11 samples.

How the data were processed

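The 11 libraries came from HEC50B, an endometrial cancer cell line. Per the labels, the parental line carries the R183W substitution in PPP2R1A, the scaffold subunit of the phosphatase PP2A, and its comparator was returned to wild type (WT) with CRISPR. Both lines received vehicle or 50 µM WM1119, an inhibitor of the lysine acetyltransferase KAT6A, for 4 days. Per the labels' protocols, RNA was isolated on RNeasy columns and treated with DNase I, and libraries were made with a ScriptSeq Complete Gold kit, while the molecule field reads polyA RNA. How these descriptions fit together is not given in the sources used here. The labels number the replicates but do not say that they are separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. Those of overlaps count genes and do not measure that spread.

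The authors deposited a table of expected counts per gene, that is, estimated counts that need not be whole. The submitters' processing notes name STAR, RSEM and the hg19 build, without versions, roles or annotation. Reads that match several genes are shared out in estimated counts, so levels of genes with near-identical paralogs or pseudogenes are uncertain, as are those of overlapping and antisense genes. The table held 57736 gene IDs, of which 51959 were matched by ID to a symbol in GENCODE release 29; the unmatched IDs held 1.01% of the counts. GENCODE was used only for names, gene types and GC content, because its build differs from that of the counts, and no coordinates are given. Mitochondrially encoded transcripts and a few other list members found no match and were not analysed here.

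Expected counts were rounded to whole numbers. Library totals ran from 2609922 in WT WM1119 library 3 to 6065149 in R183W vehicle library 1. Levels are given as CPM, counts scaled to a common library total. A count of 0 allows up to 1.15 CPM in the former and 0.495 in the latter, taking 3 counts as the floor. Floors and counting intervals cover counting error only. CPM values were scaled with TMM factors. Genes were kept by filterByExpr, which left 13980 genes holding at least 99.7% of the counts of every library.

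Differential expression was tested with edgeR 4.0.16 (quasi-likelihood F test, two-sided) in R 4.3.3. A single fit with 4 group means and all 11 libraries gave a biological coefficient of variation of 19.6%. It took the spread of each gene to be common to the 4 groups, which was not tested. No replicate block entered this fit. The comparisons were WM1119 against vehicle in each genotype, R183W against WT under each treatment, and the interaction, which is the inhibitor effect in R183W cells less that in WT cells. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2 scale with standard errors (SE); levels are mean CPM ± SD.

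The design, the alternatives, the rule for named genes and 40 gene lists were fixed before the data were examined, and 37 lists had at least 3 members among the genes tested. Lists were tested with camera in limma 3.58.1 with a correlation preset at 0.01, adjusted over the lists of a comparison. Camera sets the members of a list against the other genes tested. With the preset its p-values thus rest on the number of genes and are not a measure of the spread between libraries alone. Camera was repeated with a correlation estimated for each list, and fry was run as a further alternative. A call lost in the camera repeat does not by itself show correlated members, because the estimate could lie below the preset. For the DNA replication and S phase interaction the estimate was -0.0115, yet the camera adjusted p went from 7.79e-33 to 6.86e-05. For each list, calls were also counted after adjustment over its members alone. Where a list is described, "higher" and "lower" count members called over all genes tested.

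Named genes were PPP2R1A, KAT6A and members of the KAT6A/KAT6B complex and CDK inhibitor lists. To these were added, for each comparison, the 10 largest changes in each direction among called genes with at least 2 CPM in the higher group and no overlap between the libraries compared; the interaction had no overlap condition. Up to 4 called members of each list with the largest changes completed the set. Clone, locus, pseudogene and small RNA names were passed over. Some genes so selected are not reported here, though all totals and list results include them. For genes with 0 counts in a group, a fold is given only as a lower bound at 3 counts over the group.

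On simulated counts with the real means and library sizes, genes changed by 1.5-, 2- and 4-fold were recovered at 8.96%, 35.8% and 89.4% for the inhibitor in R183W cells. The shares were 4.48%, 31.3% and 80.3% for the inhibitor in WT cells, 10.4%, 31.3% and 78.8% for genotype under vehicle, and 7.46%, 29.9% and 74.2% for genotype under WM1119. For the interaction they were 1.49%, 11.9% and 51.5%. False calls made up 6.32%, 9.41%, 5.88%, 5.13% and 2.27% of the calls in the same order. All but the interaction lay above the 5% aimed at. Each share rests on a single simulated data set with 44 to 95 calls, too few to tell whether it truly differs from 5%. A list planted at 1.5-fold was called in each comparison, and 0 of the 36 other lists were. Genes were simulated independently of each other, with a spread common to all groups. The lack of other list calls therefore does not show how often lists with correlated members are falsely called.

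Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, only the groups compared, a fold change of at least 2, and leaving out each library in turn. A correction of each library's trend on GC content, leaving out libraries for lists and overlaps, and the alternatives for the overlap in WT cells, were added after seeing the data. The GC correction covered 97.1% of the genes tested. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for gene properties and plots.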

Results

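Gene expression was measured by RNA-seq in HEC50B cells with parental PPP2R1A R183W or CRISPR-restored WT PPP2R1A, each given vehicle or the KAT6A inhibitor WM1119 for 4 days. There were 3 libraries in each group except R183W cells with WM1119, which had 2. Totals were 6065149, 4576026 and 4805210 counts in R183W vehicle libraries and 4545499, 5212326 and 5261548 in WT vehicle libraries. They were 4152250 and 3323979 in R183W WM1119 libraries and 4511680, 3932391 and 2609922 in WT WM1119 libraries.

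The libraries separated by genotype and treatment, apart from 1 library. On the first principal component, with 32.9% of the variance, R183W libraries scored -56.1 to -22.8 and 5 of the 6 WT libraries scored 26.6 to 54.3. WT WM1119 library 3 scored -10.4 there and -78.2 on the second component, which held 23.4%. Its log CPM correlated with the other members of its group at 0.917 and 0.937, while other replicate pairs correlated at 0.957 to 0.975, across genes, which are not independent replicates. None of the 10 pairs of libraries within a group matched within sampling noise (chi-square per degree of freedom 2.68 to 25.3).

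**Figure D1:**
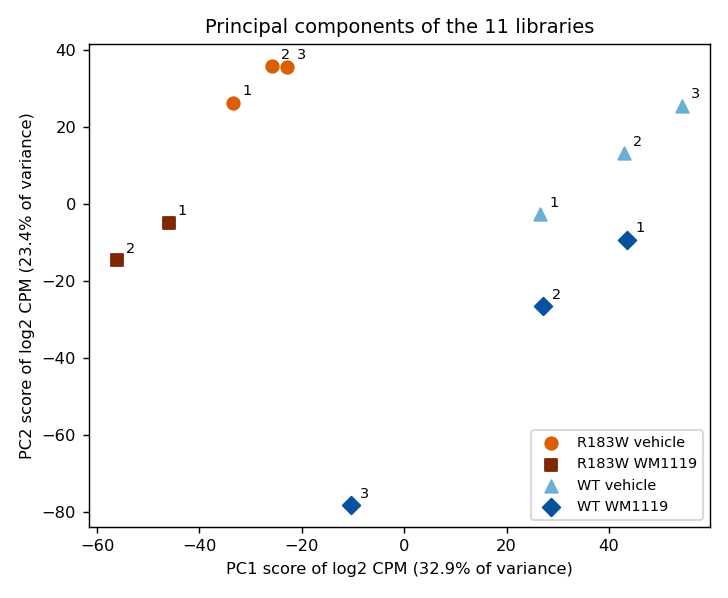
First and second principal components of log2 CPM, 1 point per library, numbered by replicate; colour and shape mark the 4 groups. R183W libraries lie on the left and WT libraries on the right, except WT WM1119 library 3. It lies apart at -10.4 on the first and -78.2 on the second component.

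The edited gene and the drug target were examined first. The edit changes a codon, which gene counts cannot show. PPP2R1A (ENSG00000105568) stood at 34.3 ± 2.86 CPM (SD, n = 3) in R183W and 23.2 ± 2.69 (n = 3) in WT cells under vehicle, a log2 difference of 0.56 (SE 0.17, edgeR adjusted p = 0.0463). That call held without WT WM1119 library 1 (edgeR adjusted p = 0.044) or 3 (0.0162); leaving out any of the other 9 libraries gave 0.0576 to 0.178. It was also lost with no filter (0.0908) and after GC correction (0.116). KAT6A (ENSG00000083168) read 170 ± 26.3 CPM under vehicle and 179 ± 7 (n = 2) with WM1119 in R183W cells, a log2 change of 0.07 (SE 0.21, edgeR adjusted p = 0.895). In WT cells it read 149 ± 28.8 and 223 ± 53.9, a log2 change of 0.58 (SE 0.18, edgeR adjusted p = 0.0896). Over the 8 genes of the KAT6A/KAT6B complex, the acetyltransferases and their scaffold proteins, the median log2 change with WM1119 was 0.15 in R183W and 0.20 in WT cells (camera adjusted p = 0.312 and 0.179). In WT cells 3 of them (KAT6A, KAT6B and ING5) passed when adjusted over the list alone. CDKN2A and CDKN2B, inhibitors of cell cycle kinases, had 0 counts in all 11 libraries, which allows up to 1.15 CPM in the shallowest.

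The first comparison asked what WM1119 did in cells with the mutant scaffold subunit. Gene counts do not show KAT6A activity, so no change below was traced to KAT6A itself. With WM1119, R183W cells raised targets of NRF2, the regulator of the oxidative stress response, and lowered targets of YAP and TEAD together with genes of DNA replication, homologous recombination, secreted factors, hypoxia and amino acid supply. Of 18 NRF2 targets, 9 rose (12 higher adjusted over the list alone; median 0.82, camera adjusted p = 2.93e-11). AKR1C3, an aldo-keto reductase, rose from 26.6 ± 2.1 (n = 3) to 106 ± 8.29 CPM (n = 2), a log2 change of 2.00 (SE 0.15, edgeR adjusted p = 9.32e-06). FTL, the ferritin light chain, rose from 876 ± 48.1 to 2070 ± 28.3 CPM, a log2 change of 1.24 (SE 0.11, edgeR adjusted p = 3.38e-05). AKR1C3 has close paralogs and FTL has pseudogenes, so the assignment of their reads is uncertain. The count of NRF2 targets that rose was 4 without R183W vehicle library 2 or 3 or R183W WM1119 library 2, and 2 without R183W WM1119 library 1. Cholesterol synthesis genes had a median of 0.29, with 2 of 22 higher (3 adjusted over the list alone; camera adjusted p = 0.00231). INSIG1, a sterol-regulated brake on that pathway, rose from 67.5 ± 3.15 to 151 ± 0.584 CPM, a log2 change of 1.16 (SE 0.16, edgeR adjusted p = 0.00113). The cholesterol count was 1 without either R183W WM1119 library and 4 without WT WM1119 library 3.

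Interferon-stimulated genes also leaned upward, with 6 of 24 higher (11 higher and 1 lower adjusted over the list alone; median 0.75, camera adjusted p = 0.000806). The list's call was lost at an adjusted p = 0.0537 with an estimated correlation. With genes at 0 counts in a group set to their bound and 3 members under the floor left out, the median was 0.82. IFIT3, an antiviral effector, rose from 6.27 ± 0.158 to 14.4 ± 3.09 CPM, a log2 change of 1.19 (SE 0.23, edgeR adjusted p = 0.00915), with an adjusted p of 0.176 without R183W WM1119 library 2. The median of the interferon-stimulated genes was 0.10, over 26 members, without R183W WM1119 library 1, though the list passed the preset test with each library left out in turn. Their count was 2 without that library or R183W vehicle library 1 or 3, 3 without R183W vehicle library 2, and 1 without R183W WM1119 library 2.

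YAP/TEAD targets, which respond to cell tension and Hippo signalling, fell in 6 of 15 cases (12 adjusted over the list alone; median -1.01, camera adjusted p = 3.05e-09). ANKRD1, a classical target, fell from 202 ± 24.7 to 12.2 ± 0.111 CPM, a log2 change of -4.05 (SE 0.18, edgeR adjusted p = 4.32e-08). The receptor tyrosine kinase AXL changed by -1.45 (SE 0.20, edgeR adjusted p = 0.00113). The YAP/TEAD count was 3 without R183W vehicle library 3 or R183W WM1119 library 1 and 2 without R183W WM1119 library 2. Senescence-associated secretory factors fell in 7 of 16 cases (8 adjusted over the list alone; median -1.15, camera adjusted p = 1.14e-06). Among them PLAT, tissue plasminogen activator, fell from 24.2 ± 4.14 to 5.87 ± 0.184 CPM, and MMP1, a collagenase, went from 44 counts to 0 and was at least 7-fold lower (edgeR adjusted p = 0.0201). The MMP1 call was lost without R183W vehicle library 1 (0.0507) or 3 (0.0515) or R183W WM1119 library 1 (0.156) or 2 (0.154). The secretory count was 4 and 3 without R183W WM1119 libraries 1 and 2. The cytokine IL11, outside that list, changed by -4.19 (SE 0.49, edgeR adjusted p = 0.000388).

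DNA replication and S phase genes fell in 8 of 39 cases (15 adjusted over the list alone; median -0.56, camera adjusted p = 4.47e-09). RFC2, a clamp loader subunit, changed by -0.94 (SE 0.18, edgeR adjusted p = 0.00973), and its adjusted p was 0.0925 and 0.136 without R183W WM1119 library 1 or 2. The DNA replication and S phase count was 4, 1 and 3 without R183W vehicle libraries 1, 2 and 3, and 20 without WT WM1119 library 3. It was 0 by edgeR without R183W WM1119 library 1 or 2, where 13 and 14 members were lower at an unadjusted p under 0.05. Homologous recombination and Fanconi repair genes had a median of -0.57 (camera adjusted p = 3.7e-06), with 2 of 21 lower and 5 adjusted over the list alone. That count ranged from 0 by edgeR, without R183W vehicle library 3 or either R183W WM1119 library (6 to 7 lower at an unadjusted p under 0.05), to 6 without WT WM1119 library 3. Mitosis genes had a median of -0.26 (camera adjusted p = 8.85e-06; adjusted p = 0.0529 with an estimated correlation), with 2 of 34 lower and 3 adjusted over the list alone. Without either R183W WM1119 library or R183W vehicle library 2 or 3, the mitosis count was 0 by edgeR, with 4 to 10 lower at an unadjusted p under 0.05, and without WT WM1119 library 3 it was 6.

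Hypoxia and glycolysis genes had 4 of 20 lower (6 adjusted over the list alone; median -0.49, camera adjusted p = 2.56e-05), including NDRG1, a hypoxia-induced gene, which fell from 140 ± 5.53 to 33.6 ± 0.334 CPM. ATF4 and amino acid response genes had 4 of 24 lower and 1 higher (7 and 1 adjusted over the list alone; median -0.35, camera adjusted p = 2.76e-05). ASNS, asparagine synthetase, fell from 938 ± 6.1 to 443 ± 11.1 CPM, a log2 change of -1.08 (SE 0.12, edgeR adjusted p = 0.000278). The hypoxia count was 1 without R183W WM1119 library 1, 2 without R183W WM1119 library 2 or R183W vehicle library 2 or 3, and 9 without WT WM1119 library 3. The lower ATF4 count was 1 without R183W WM1119 library 1, 2 without R183W WM1119 library 2 or any R183W vehicle library, and 9 without WT WM1119 library 3. Immediate early genes (median -0.70, camera adjusted p = 0.00131) and ribosome biogenesis genes (median -0.27, 0.0022) also passed. ERK pathway feedback genes (median -0.32, camera adjusted p = 0.0136), lysosome genes (0.22, 0.0191), other lysine acetyltransferases (0.42, 0.0246) and MHC class I presentation genes (0.35, 0.0371) passed with the preset only. Each of these last 4 lists missed 0.05 without R183W WM1119 library 1, at adjusted p = 0.0723, 0.0793, 0.0605 and 0.0793, and the MHC class I list also without R183W vehicle library 1 (0.091) and after GC correction (0.0727). With an estimated correlation the adjusted p-values were 0.0537, 0.145, 0.0851 and 0.0941. Of 15 epithelial genes, 3 rose; CLDN3, a tight junction claudin, went from 2.77 ± 1.2 to 33.4 ± 4.08 CPM, a log2 change of 3.54 (SE 0.35, edgeR adjusted p = 7.16e-05), and the adhesion molecule EPCAM changed by 1.07 (SE 0.16, 0.00162). The epithelial list itself did not pass (3 higher and 1 lower adjusted over the list alone, median -0.1, camera adjusted p = 0.422).

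In all, edgeR called 649 genes in R183W cells with WM1119, 278 higher and 371 lower, of which 145 and 232 changed at least 2-fold. DESeq2 called 975 and limma-voom 649. The number was 419, 264 and 275 without R183W vehicle libraries 1, 2 and 3, 130 and 118 without R183W WM1119 libraries 1 and 2, and 1600 without WT WM1119 library 3, which kept all 649. A fit of only these groups called 2406.

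The same treatment was then examined in WT cells. There WM1119 raised DNA replication genes and lowered YAP/TEAD targets, the only lists that also passed with an estimated correlation. Secreted factors and ERK feedback genes were lower with the preset correlation alone (adjusted p = 0.064 and 0.0523 with an estimated correlation). Of 39 DNA replication and S phase genes, 14 rose (22 adjusted over the list alone; median 0.61, camera adjusted p = 3.5e-12). POLD1, the catalytic subunit of polymerase delta, rose from 10.4 ± 3.24 to 28 ± 5.41 CPM (n = 3 each), a log2 change of 1.43 (SE 0.26, edgeR adjusted p = 0.00782). CDT1, which loads the replicative helicase, rose from 33.9 ± 9.01 to 74.1 ± 15.7 CPM, a log2 change of 1.12 (SE 0.21, edgeR adjusted p = 0.00863). The DNA replication and S phase count was 5 and 6 without WT vehicle libraries 2 and 3 and 8 without WT WM1119 library 2. Without WT WM1119 library 3 it was 16. Homologous recombination and Fanconi repair genes had a median of 0.34 (camera adjusted p = 0.00306; adjusted p = 0.0523 with an estimated correlation), with 2 of 21 higher and 6 adjusted over the list alone. Their count was 0 by edgeR without WT vehicle library 2 or 3, WT WM1119 library 2 or R183W vehicle library 2 or 3 (5 to 7 higher at an unadjusted p under 0.05), 1 without either R183W WM1119 library, and 4 without WT WM1119 library 1. Interferon-stimulated genes had 4 of 24 higher (4 adjusted over the list alone; median 0.47, camera adjusted p = 5.16e-05; adjusted p = 0.0523 with an estimated correlation). Among them ISG15, a ubiquitin-like modifier, rose from 40.6 ± 18.6 to 141 ± 45.1 CPM, a log2 change of 1.80 (SE 0.31, edgeR adjusted p = 0.00539). The interferon count was 2 without WT vehicle library 2 or 3 or WT WM1119 library 2.

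YAP/TEAD targets had a median of -0.60 in WT cells (camera adjusted p = 3.55e-06), with 2 of 15 lower and 7 adjusted over the list alone. ANKRD1 fell from 114 ± 8.36 to 15 ± 0.318 CPM, a log2 change of -2.93 (SE 0.15, edgeR adjusted p = 2.23e-07). The YAP/TEAD count was 1 without WT vehicle library 2, 5 without WT WM1119 library 1 and 4 without WT WM1119 library 3. Senescence-associated secretory factors had 6 of 16 lower (9 lower and 1 higher adjusted over the list alone; median -0.85, camera adjusted p = 2.08e-05; adjusted p = 0.064 with an estimated correlation). AREG, a ligand of the EGF receptor, fell from 76.7 ± 20.9 to 13.3 ± 3.72 CPM, and GDF15, a stress-induced cytokine, from 2100 ± 103 to 847 ± 28.3 CPM. ERK pathway feedback genes had 4 of 17 lower (5 lower and 1 higher adjusted over the list alone; median -0.34, camera adjusted p = 0.00408; adjusted p = 0.0523 with an estimated correlation). They included FOSL1, an AP-1 subunit, with a change of -2.32 (SE 0.16, edgeR adjusted p = 4.54e-06). Immediate early genes (median -0.49, camera adjusted p = 0.00201), hypoxia and glycolysis genes (-0.40, 0.0129) and NF-kB targets (-0.19, 0.019) passed with the preset, and stood at adjusted p = 0.0523, 0.064 and 0.0778 with an estimated correlation. Mesenchymal genes and fibroblast and stromal markers had medians of -0.14 and -0.75 (camera adjusted p = 0.0448 for each; adjusted p = 0.123 and 0.27 with an estimated correlation). The mesenchymal call was lost without R183W vehicle library 1 (0.0507), WT vehicle library 1 (0.0934) or WT WM1119 library 3 (0.0534). The fibroblast call was lost without R183W vehicle library 1 (0.0507), WT vehicle library 2 (0.0731) or 3 (0.0788) or WT WM1119 library 3 (0.205), and with fry (0.0506). NRF2 targets did not pass in WT cells (median 0.24, camera adjusted p = 0.15), nor did mitosis genes (-0.03, 0.423).

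CLDN3 rose in WT cells from 6.27 ± 2.87 to 73.4 ± 13.5 CPM, and AKR1C3 from 31.6 ± 0.868 to 68.8 ± 6.86 CPM, log2 changes of 3.54 (SE 0.30, edgeR adjusted p = 1.8e-05) and 1.12 (SE 0.14, 0.000656). CDKN1C, a CDK inhibitor, fell from 37.3 ± 2.23 to 19.4 ± 1.82 CPM, a log2 change of -0.93 (SE 0.17, edgeR adjusted p = 0.00821). In all 680 genes were called, 326 higher and 354 lower, of which 125 and 184 changed at least 2-fold. DESeq2 called 1115 and limma-voom 627. The number was 260 and 247 without WT vehicle libraries 2 and 3, 272 without WT WM1119 library 2 and 1392 without WT WM1119 library 1. Without WT WM1119 library 3 it was 842, with 574 of the 680 kept, and a fit of only these groups called 139. Those 139 were the only ones of the 680 to hold without the R183W libraries in the fit. Most calls in WT cells thus depended on a spread shared with R183W cells.

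**Figure D2:**
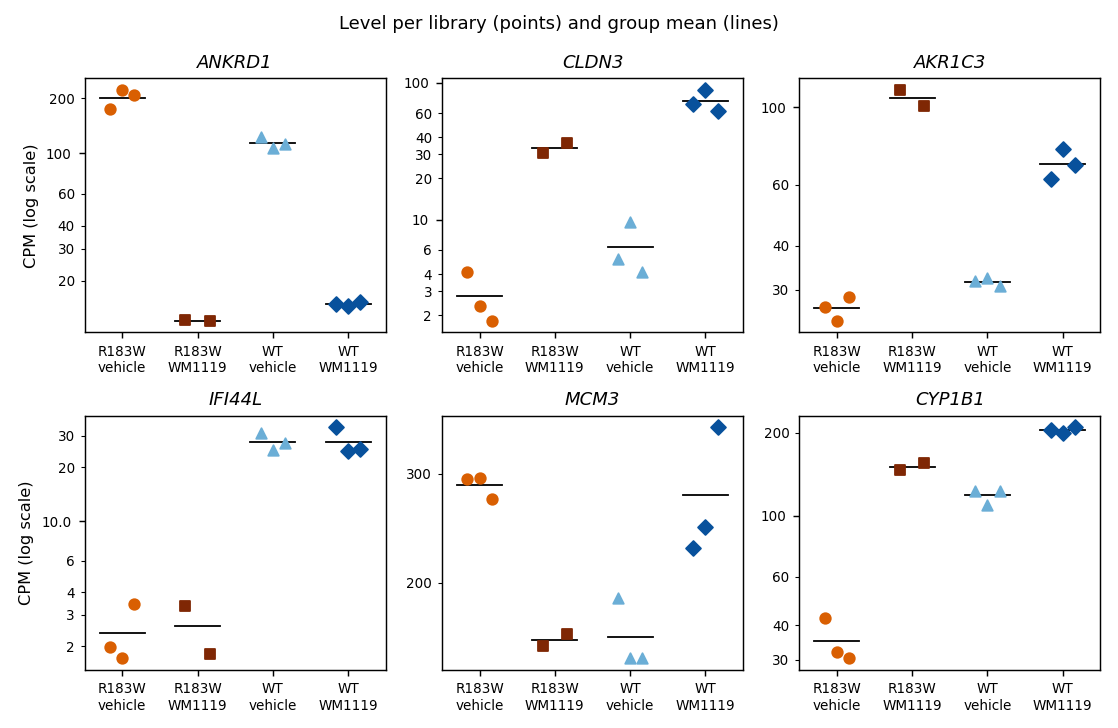
Level of 6 genes in CPM on a log axis, with 1 point per library and a line at each group mean. ANKRD1 was lower and CLDN3, AKR1C3 and CYP1B1 were higher with WM1119 in both genotypes, IFI44L was lower in R183W cells under both treatments, and MCM3 was 161 CPM in R183W and 277 CPM in WT cells with WM1119.

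The inhibitor responses of the 2 genotypes, which share no library, were then set side by side. Among 13980 genes, 91 rose in both and 140 fell in both, against 6.48 and 9.39 for independent sets (exact hypergeometric p = 1.62e-81 and 5.37e-134, with genes taken as independent). Called in opposite directions were 3 genes that rose in R183W and fell in WT cells, against 7.04 for independent sets. The reverse held for 8 genes, near the 8.65 for independent sets (exact hypergeometric p = 0.639). Genes lower in both included ANKRD1, FOSL1, the phosphatase DUSP5 and the p53-responsive kinase PLK2, and those higher in both included CLDN3, AKR1C3 and CYP1B1, a cytochrome P450. Of the 649 genes called in R183W cells, 570 (87.8%) had the same sign in WT cells, and of the 680 called in WT cells, 593 (87.2%) had the same sign in R183W cells. Across genes the fold changes correlated at r = 0.375 (Spearman rho = 0.408), and genes are not independent replicates. The genes higher in both numbered 25 without R183W WM1119 library 2 and 155 without WT WM1119 library 1, the lowest and highest of the fits that left out a library. They numbered 28 without R183W WM1119 library 1 and 37 to 43 without R183W vehicle library 2 or 3, WT vehicle library 2 or 3 or WT WM1119 library 2. Those lower in both ranged from 50 without either R183W WM1119 library to 227 without WT WM1119 library 3, with 77 to 81 without R183W vehicle library 2 or 3, WT vehicle library 2 or 3 or WT WM1119 library 2.

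**Figure D3:**
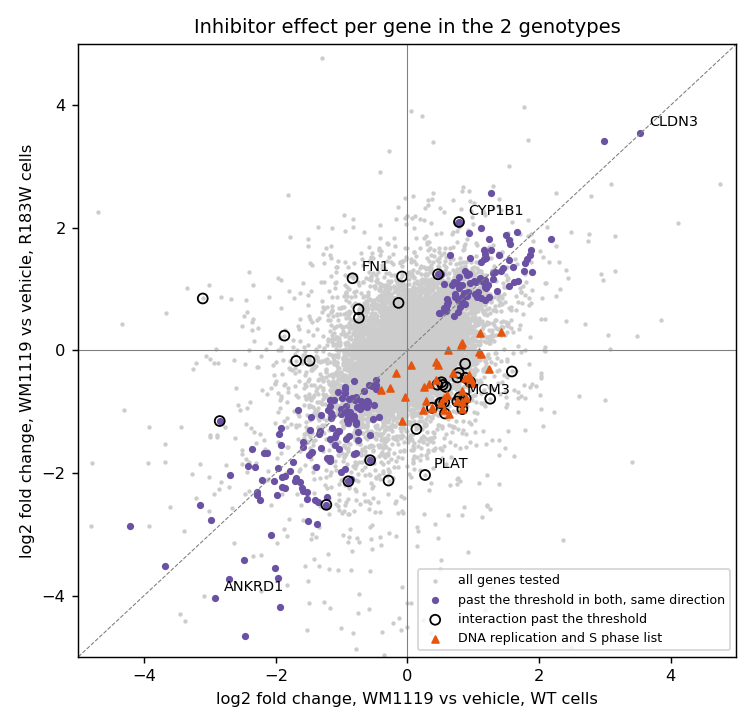
Log2 fold change with WM1119 in WT cells (horizontal) and R183W cells (vertical), 1 point per gene; 57 genes lie outside the axes. Genes called in both with the same sign (purple) follow the dashed line of equal change, and most DNA replication and S phase genes (orange triangles) lie to the lower right, higher in WT and lower in R183W cells.

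The genotype comparison under vehicle asked how R183W cells differed from WT cells without the drug. In this and every other comparison of genotypes, PPP2R1A genotype cannot be told apart from other differences between the parental and the CRISPR-edited line. The labels do not state how many clones were used. R183W cells had far lower interferon-stimulated genes and higher DNA replication, homologous recombination and cholesterol synthesis genes. Of 24 interferon-stimulated genes 15 were lower (17 adjusted over the list alone; median -1.58, also with genes at their bound; camera adjusted p = 2.47e-10). IFI44L stood at 2.38 ± 0.934 against 27.7 ± 3.14 CPM, a log2 difference of -3.53 (SE 0.29, edgeR adjusted p = 3.33e-06). Of 39 DNA replication and S phase genes 17 were higher (18 adjusted over the list alone; median 0.47, camera adjusted p = 6.42e-08), among them TK1, thymidine kinase, at 124 ± 16.3 against 55.6 ± 7.14 CPM (log2 1.15, SE 0.15, edgeR adjusted p = 0.000206). Homologous recombination and Fanconi repair genes had 4 of 21 higher (8 adjusted over the list alone; median 0.34, camera adjusted p = 0.000544). Their count was 8 without WT WM1119 library 3. Mitosis genes had 4 of 34 higher and 1 lower, and the list did not pass (camera adjusted p = 0.955). The higher mitosis count was 2 without R183W vehicle library 1 or 2 or WT vehicle library 2 or 3.

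Cholesterol synthesis genes were higher in 7 of 22 cases and lower in 1 (8 and 1 adjusted over the list alone; median 0.57, camera adjusted p = 0.000168), with FDPS, a prenyl transferase, at 1.11 (SE 0.14, edgeR adjusted p = 0.000123). Hypoxia and glycolysis genes had 5 of 20 higher (6 adjusted over the list alone; median 0.26, camera adjusted p = 0.0101; adjusted p = 0.0719 with an estimated correlation), a count of 8 without WT WM1119 library 3. NF-kB targets had 5 of 16 lower (5 adjusted over the list alone; median -0.34, camera adjusted p = 0.00199), including TNFRSF9, a receptor of the TNF family, at -1.64 (SE 0.20, edgeR adjusted p = 0.000129). Ribosomal proteins had a median of -0.34, with 9 of 37 lower and 16 adjusted over the list alone (camera adjusted p = 1.58e-05; adjusted p = 0.193 with an estimated correlation). The ribosomal protein count was 1 without any R183W vehicle library or WT vehicle library 2, 2 without WT vehicle library 3, and 16 and 18 without WT WM1119 libraries 1 and 3. Genes for PP2A subunits and regulators showed no common shift, with 3 of 27 higher and 2 lower (4 and 2 adjusted over the list alone; median 0.00, camera adjusted p = 0.957). The regulatory subunit PPP2R2C stood at 1.03 ± 0.611 against 13.2 ± 3.15 CPM, a difference of -3.60 (SE 0.43, edgeR adjusted p = 0.000113), and PPME1, the PP2A methylesterase, was higher by 0.86 (SE 0.16, 0.00347). The PP2A counts were 5 and 5 without WT WM1119 library 3, and the lower count was 1 without R183W vehicle library 1 or WT vehicle library 2.

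Single genes differed by more. INHBA, the activin beta A subunit, read 0.743 ± 0.287 CPM in R183W and 229 ± 54.1 CPM in WT cells, a log2 difference of -8.18 (SE 0.34, edgeR adjusted p = 8.53e-09). The matrix genes FN1 and LAMA4 differed by -3.06 (SE 0.19, 2.66e-07) and -2.85 (SE 0.16, 1.35e-07). FOXA2, a transcription factor of endometrial glands, read 143 ± 15.9 against 40.4 ± 0.599 CPM, a difference of 1.82 (SE 0.15, edgeR adjusted p = 3.05e-06). SEMA5A and A1CF had 182 and 104 counts in R183W cells and 0 in WT cells, at least 58.3- and 33.3-fold higher. In all 1817 genes were called, 954 higher and 863 lower in R183W cells, of which 437 and 385 differed at least 2-fold. DESeq2 called 2174 and limma-voom 2149. The number was 965, 1035 and 1144 without R183W vehicle libraries 1, 2 and 3, 968 and 1002 without WT vehicle libraries 2 and 3, and 3151 without WT WM1119 library 3, which kept 1816 of the 1817. A fit of only these groups called 2929.

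Whether WM1119 changed genotype-dependent genes in the direction of WT cells was examined in R183W cells, by sign alone, so a gene may pass the WT level. Of the genes higher in R183W cells 91 fell with WM1119, and of those lower in R183W cells 59 rose, against 25.3 and 17.2 for independent sets (exact hypergeometric p = 5.74e-28 and 2.47e-17). Genes that changed in the opposite direction, away from WT cells, numbered 25 and 52, against 19 and 22.9 (exact hypergeometric p = 0.0955 and 2.15e-08). AXL was among the 91, at 325 CPM under vehicle and 119 CPM with WM1119 in R183W cells, against 159 CPM in WT vehicle cells. ANKRD1 was too, but passed the WT level of 114 CPM, from 202 to 12.2 CPM. CYP1B1, among the 59, also passed it, from 35 to 150 CPM against 118 CPM. Both comparisons use the same 3 R183W vehicle libraries, and a fit with separate controls was not run. Part of the excess may thus come from the shared controls. In 50 simulations of unchanged groups with those controls, 0.24 and 0.28 genes were called per comparison, too few to give an overlap to compare with. Over all genes the fold changes correlated at r = -0.0775, against -0.412 in the simulations. Their covariance was -0.0482 against a simulated -0.0776 (range -0.0858 to -0.0702), a remainder of 0.0295. The simulations took their spread from all groups together, WT WM1119 library 3 included. Without that library 1600 rather than 649 genes were called with WM1119 in R183W cells. The pooled spread may thus be too wide for these controls. The remainder therefore does not show whether fold changes ran opposite beyond the shared controls. The 91 genes ranged from 21 without R183W WM1119 library 2 to 228 without WT WM1119 library 3, and were 23 without R183W WM1119 library 1, 35 to 50 without an R183W vehicle library and 52 and 59 without WT vehicle libraries 2 and 3. The 59 ranged from 15 without R183W WM1119 library 1 to 130 without WT WM1119 library 3, and were 17 without R183W WM1119 library 2, 26 to 35 without an R183W vehicle library and 37 without WT vehicle library 2.

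In WT cells the matching overlap, again by sign alone, ran in the direction of R183W cells. Of the genes higher in R183W cells 91 rose with WM1119 in WT cells, and of those lower in R183W cells 95 fell, against 22.2 and 21.9 for independent sets (exact hypergeometric p = 1.27e-32 and 4.12e-36). In the other direction there were 45 and 25 genes, against 24.2 and 20.1 (p = 3.81e-05 and 0.154, exact hypergeometric test). These comparisons share the WT vehicle libraries, so part of the overlap may come from the shared controls. The covariance of 0.142 lay above the simulated 0.0807 (range 0.0727 to 0.0945), while the correlation of r = 0.264 was below the simulated 0.485. The simulations took their spread from all groups together. WT vehicle pairs had chi-square per degree of freedom 5.14 to 13.6, against 2.68 to 7.39 for R183W vehicle pairs. The pooled spread may thus be too narrow for these controls. The covariance therefore does not show whether fold changes ran alike beyond the shared controls. The 91 genes ranged from 20 without WT vehicle library 3 to 228 without WT WM1119 library 1, and were 26 without WT vehicle library 2, 34 without WT WM1119 library 2 and 47 to 57 with an R183W library left out. The 95 ranged from 39 without WT vehicle library 2 to 154 without WT WM1119 library 1, and were 40 without WT vehicle library 3, 46 without WT WM1119 library 2 and 50 to 63 without an R183W vehicle library.

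Under WM1119 the genotypes differed again in interferon-stimulated and cholesterol synthesis genes in the direction seen under vehicle, while DNA replication genes were lower in R183W cells. Interferon-stimulated genes were lower in 10 of 24 cases (15 adjusted over the list alone; median -1.44, also with genes at their bound; camera adjusted p = 7.85e-11). IFI44L stood at 2.59 ± 1.09 CPM (n = 2) against 27.7 ± 4.89 CPM (n = 3), a difference of -3.38 (SE 0.35, edgeR adjusted p = 4.66e-05). The interferon count was 5 and 6 without R183W WM1119 libraries 1 and 2. Cholesterol synthesis genes were higher in 5 of 22 cases (12 adjusted over the list alone; median 0.60, camera adjusted p = 3.94e-08), a count of 10 without WT WM1119 library 3. INSIG1 stood at 151 ± 0.584 against 42.2 ± 2.29 CPM, a difference of 1.83 (SE 0.16, edgeR adjusted p = 1.25e-05). NRF2 targets were higher in 5 of 18 cases (9 adjusted over the list alone; median 0.41, camera adjusted p = 3.1e-05), with GCLM, a subunit of the enzyme that starts glutathione synthesis, at 1.11 (SE 0.21, edgeR adjusted p = 0.00449; 0.066 without R183W WM1119 library 2). The NRF2 count was 3 and 2 without R183W WM1119 libraries 1 and 2 and 8 without WT WM1119 library 3.

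DNA replication and S phase genes were lower in 5 of 39 cases under WM1119 (17 adjusted over the list alone; median -0.60, camera adjusted p = 3.94e-08). Their count was 1 without R183W WM1119 library 1, 13 without WT WM1119 library 3, and 0 by edgeR without R183W WM1119 library 2, where 14 members were lower at an unadjusted p under 0.05. RRM2, a ribonucleotide reductase subunit, differed by -1.09 (SE 0.19, edgeR adjusted p = 0.00277), with an adjusted p of 0.066 without R183W WM1119 library 2. Homologous recombination and Fanconi repair genes (median -0.39, camera adjusted p = 0.0054), mitosis genes (-0.23, 0.00892), ATF4 and amino acid response genes (-0.28, 0.0137), senescence-associated secretory factors (-0.54, or -0.44 with genes at their bound; 0.00533) and ribosomal proteins (-0.32, 3.1e-05) also passed with the preset. They stood at adjusted p = 0.107, 0.248, 0.103, 0.235 and 0.192 with an estimated correlation. NF-kB targets (-0.23, camera adjusted p = 0.0337) and fatty acid synthesis genes (0.31, 0.0279) stood at adjusted p = 0.13 each with an estimated correlation. The NF-kB call was lost without R183W WM1119 library 1 (0.0544) or WT WM1119 library 1 (0.0576) or 3 (0.0675), and the fatty acid call without R183W WM1119 library 1 (0.0966) or WT WM1119 library 3 (0.11). Among single genes NOSTRIN, which regulates nitric oxide synthase, stood at 347 ± 6.04 against 8.22 ± 1.76 CPM and FLG, filaggrin, at 1.93 ± 0.69 against 250 ± 38.9 CPM.

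Under WM1119 edgeR called 1197 genes between genotypes, 649 higher and 548 lower in R183W cells, of which 382 and 338 differed at least 2-fold. DESeq2 called 1510 and limma-voom 1088. The number was 386 and 394 without R183W WM1119 libraries 1 and 2, 749 without WT WM1119 library 2 and 2895 without WT WM1119 library 3, which kept 1193 of the 1197. A fit of only these groups called 319 and kept 318 of the 1197. Of the genes called under vehicle, 354 higher and 317 lower in R183W cells were called in the same direction under WM1119, against 44.3 and 33.8 for independent sets, and 1668 of 1817 (91.8%) had the same sign.

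The interaction tested whether the inhibitor effect differed by genotype. DNA replication genes separated the genotypes most clearly, falling in R183W and rising in WT cells. The DNA replication and S phase list had a median interaction of -1.18 (camera adjusted p = 7.79e-33; 6.86e-05 with an estimated correlation), with 8 of 39 members lower and 27 adjusted over the list alone. MCM3 went from 288 ± 12.8 to 161 ± 4.96 CPM with WM1119 in R183W cells and from 163 ± 22.3 to 277 ± 69.5 CPM in WT cells, an interaction of -1.59 (SE 0.25, edgeR adjusted p = 0.02). MCM7, of the same helicase, and CDC6, which loads it, had interactions of -1.67 (SE 0.24, 0.0148) and -1.79 (SE 0.29, 0.023). All 3 lost their calls without R183W vehicle library 2 or 3 or either R183W WM1119 library (0.0503 to 0.2), MCM3 and CDC6 also without WT vehicle library 2 (0.0525 and 0.0595), MCM3 without WT vehicle library 3 (0.0562), and CDC6 without R183W vehicle library 1 (0.0542) or WT WM1119 library 2 (0.0611). The mean log2 CPM over the list was 5.31 to 5.38 in R183W vehicle, 4.83 to 4.84 in R183W WM1119, 4.77 to 4.83 in WT vehicle and 5.26 to 5.42 in WT WM1119 libraries. Over fits that left out a library the DNA replication and S phase median stayed between -1.28 and -1.15, and was -1.15 without WT WM1119 library 3. The number of members called was 3 without R183W vehicle library 1, 1 and 2 without WT vehicle libraries 2 and 3, 3 without WT WM1119 library 2 and 18 without WT WM1119 library 3. It was 0 by edgeR without R183W vehicle library 2 or 3 or R183W WM1119 library 1 or 2, where 28, 28, 24 and 26 members were lower at an unadjusted p under 0.05.

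**Figure D4:**
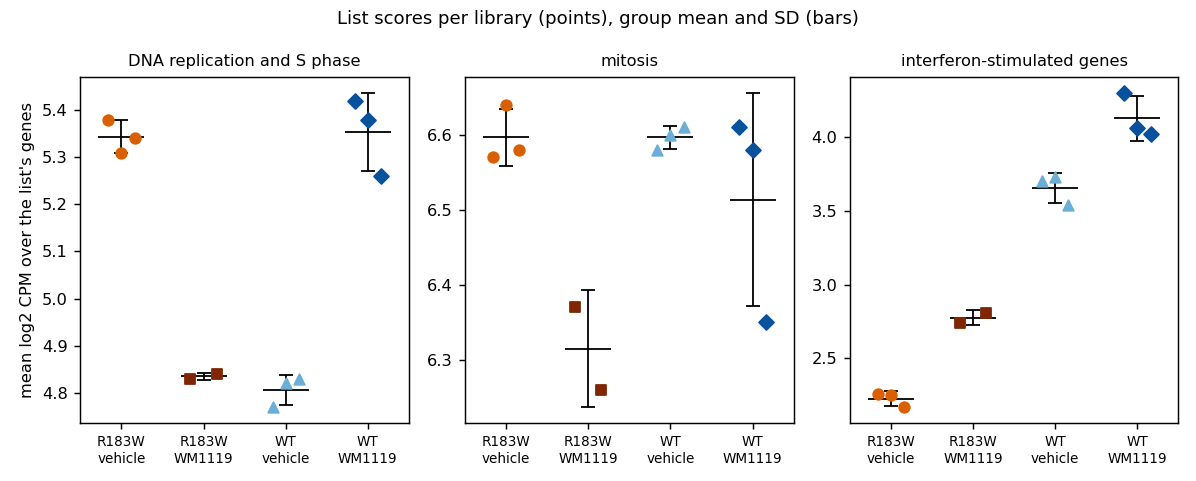
Mean log2 CPM over the DNA replication, mitosis and interferon lists, 1 point per library, with bars at the group mean and SD. Replication scores were lower with WM1119 in R183W cells and higher in WT cells, and interferon scores were higher in WT cells under both treatments.

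Homologous recombination and Fanconi repair genes had a median interaction of -0.94 (camera adjusted p = 4.36e-13), with 1 of 21 lower and 11 adjusted over the list alone. The called gene, FANCD2, had an interaction of -1.10 (SE 0.20, edgeR adjusted p = 0.0361), and lost its call without any R183W library, WT vehicle library 2 or 3 or WT WM1119 library 2 (0.0854 to 0.317). NRF2 targets had a median of 0.66 (camera adjusted p = 6.09e-10), with 1 of 18 higher, FTL at 0.78 (SE 0.15, edgeR adjusted p = 0.0486), and 8 adjusted over the list alone. FTL lost its call without any library except WT WM1119 library 3 (0.069 to 0.295), where 2 targets were called. ATF4 and amino acid response genes had a median of -0.25 (camera adjusted p = 1.24e-05), with 7 of 24 lower adjusted over the list alone. These 3 lists passed with an estimated correlation too, at adjusted p = 0.00145, 0.00236 and 0.00972. Mitosis genes (median -0.24, camera adjusted p = 0.000844), YAP/TEAD targets (-0.23, 0.0261), MHC class I presentation genes (0.24, 0.0322) and heat shock genes (-0.28, 0.0489) stood at adjusted p = 0.174, 0.137, 0.141 and 0.161 with an estimated correlation, and the mitosis call was also lost with fry (0.094). The YAP/TEAD call was lost without WT vehicle library 1 (0.0562), R183W WM1119 library 1 (0.0581) or WT WM1119 library 1 (0.0727). The MHC class I call was lost without R183W vehicle library 1 (0.0564) or 3 (0.0511), R183W WM1119 library 1 (0.0661) or WT WM1119 library 2 (0.052). The heat shock call was lost without R183W vehicle library 2 (0.0899) or 3 (0.109), WT vehicle library 1 (0.0953) or 2 (0.0717), R183W WM1119 library 2 (0.248) or WT WM1119 library 1 (0.166) or 2 (0.0559). Interferon-stimulated genes had a median interaction of 0.10 and did not pass (camera adjusted p = 0.672).

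Single genes with a larger inhibitor effect in R183W cells included FN1, fibronectin, with an interaction of 2.01 (SE 0.27, edgeR adjusted p = 0.0148). It rose from 68 ± 6.32 to 154 ± 4.28 CPM in R183W cells and fell from 566 ± 86.3 to 317 ± 81.7 CPM in WT cells. PLAT had an interaction of -2.30 (SE 0.32, edgeR adjusted p = 0.0148), going from 24.2 ± 4.14 to 5.87 ± 0.184 CPM in R183W cells and from 19.1 ± 2.39 to 23 ± 0.559 CPM in WT cells. JAG1, a Notch ligand, had an interaction of 1.41 (SE 0.20, 0.0148). Each of these 3 lost its call without R183W vehicle library 2 or 3 or either R183W WM1119 library, at adjusted p-values from 0.0503 to 0.13. The FN1 rise in R183W cells was lost without R183W WM1119 library 1 (0.0573) or 2 (0.0759), and its fall in WT cells without WT vehicle library 2 (0.0844) or 3 (0.0774) or WT WM1119 library 2 (0.0516). In all 40 genes were called, 13 with a more positive and 27 with a more negative effect in R183W cells, while 1300 had an unadjusted p under 0.05. DESeq2 called 169 and limma-voom 37. The number was 20 without R183W vehicle library 1, 12 and 13 without WT vehicle libraries 2 and 3, 2 and 1 without R183W WM1119 libraries 1 and 2, 13 without WT WM1119 library 2 and 192 without WT WM1119 library 3, which kept all 40. It was 0 by edgeR without R183W vehicle library 2 or 3, with 1076 and 1125 genes at an unadjusted p under 0.05.

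**Figure D5:**
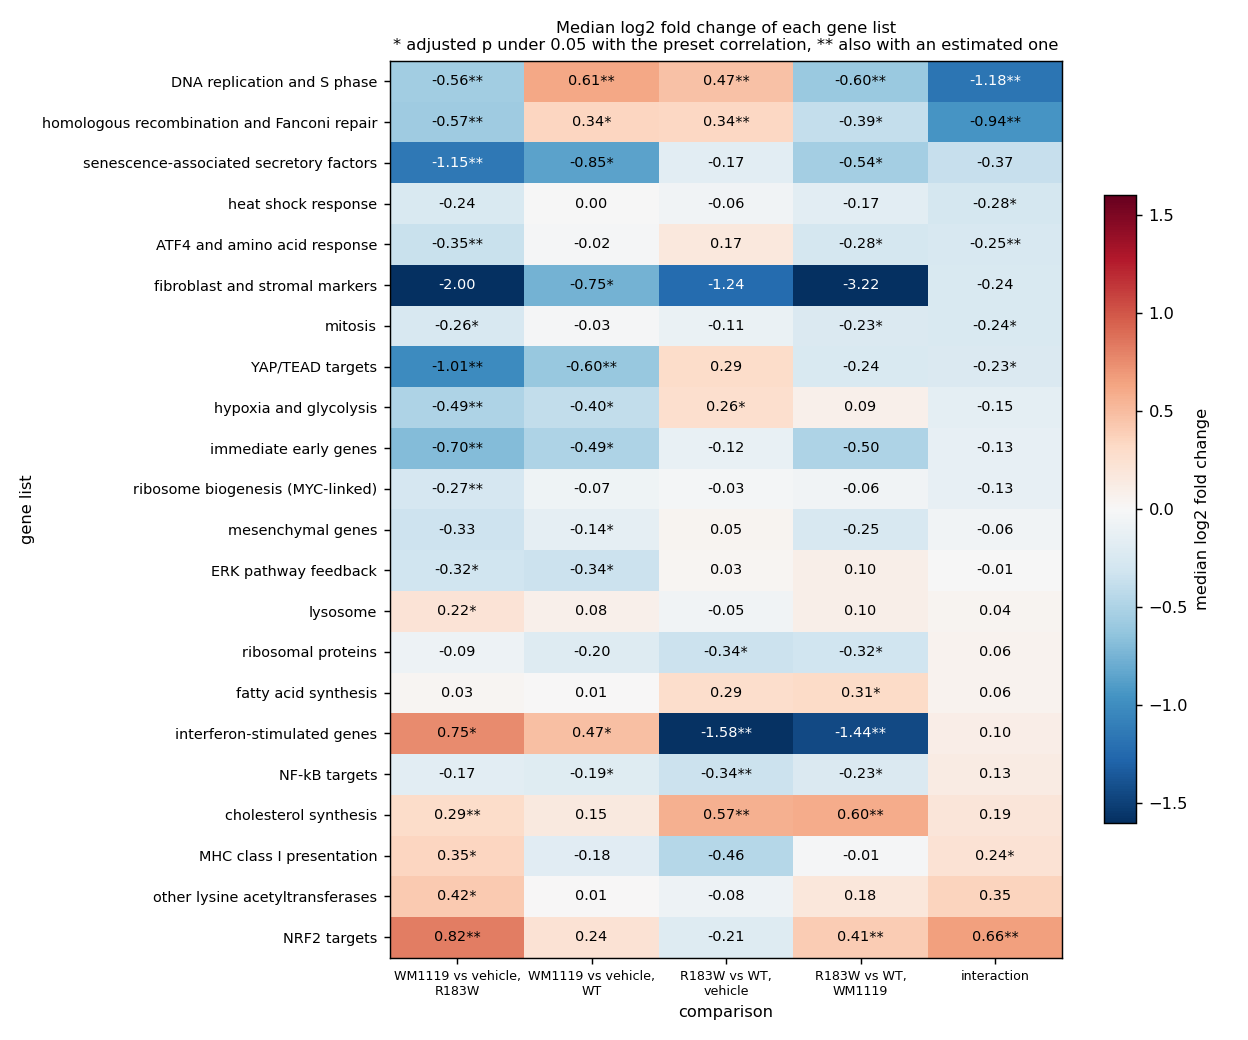
Median log2 fold change of the 22 gene lists past the threshold in any comparison, by comparison; red is higher and blue is lower with WM1119, in R183W cells or for the interaction, with 1 star for the preset and 2 for the estimated correlation. DNA replication and S phase ran from -0.56 in R183W to 0.61 in WT cells with WM1119.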

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

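Of the tests on the patterns below, the exchange of treatment labels, the share of cycling cells and the admixture of R183W cells were chosen only after the result was seen, and the GC correction behind 2 others was added at that stage too. The label exchange test took the place of an earlier test, leaving out WT WM1119 library 3, whose value is given here as well.

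DNA replication genes fell with WM1119 in R183W cells and rose in WT cells. After GC correction the median interaction of the DNA replication and S phase list was -1.17 (SE of the corrected mean list score 0.06), which speaks against GC bias, and without WT WM1119 library 3 it was -1.15. Exchanged vehicle and WM1119 labels in WT cells would turn the other responses around as well. Yet 87.8% of the genes called in R183W cells had the same sign in WT cells. The lower limit of 85.1 takes genes as independent, which they are not. A different share of cycling cells was taken to move mitosis and replication genes alike. The median interaction of mitosis genes exceeded that of the replication genes by 0.94 (SE of the same difference in mean list scores 0.07). This speaks against a share that moves both lists alike, but that premise was not tested. The mean mitosis score changed with WM1119 by -0.28 (SE 0.08) in R183W and -0.08 (SE 0.07) in WT cells, so a lesser part for cycling cells remains open. Other biological explanations were not tested.

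WT WM1119 library 3 stood apart from its group. Lower depth does not account for it, because libraries 1 and 2 thinned to its total still correlated better with each other than with it, by 0.0239 (SD 0.00041 over 20 thinnings). Reads shared with processed pseudogenes remain open, at a deviation of -0.17 (SD 0.072 over 8 other libraries). The 4 genes confined to R183W cells had 1 count in WT WM1119 library 3, or 0.681% of their R183W WM1119 level (upper limit 3.8). They stood at 0% and 1.27% in libraries 1 and 2. This speaks against admixture of R183W cells beyond that limit, as far as 4 genes can show. Why library 3 stood apart was not tested further.

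Interferon-stimulated genes were lower in R183W cells, while with WM1119 only 6 of 24 rose in R183W and 4 of 24 in WT cells. Both inhibitor calls of the list were lost with an estimated correlation (adjusted p = 0.0537 and 0.0523), and the R183W median was 0.10 without R183W WM1119 library 1. The R183W call held with each library left out, and the mean list score was 2.74 and 2.81 with WM1119 against 2.17 to 2.26 under vehicle, a difference of 0.55 (SE 0.09). After GC correction the median under vehicle was -1.62 (SE of the corrected mean list score 0.08), which speaks against GC bias. Differences between clones or isolates that do not come from PPP2R1A were not tested, and the labels do not state how many clones were used.

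For WM1119 in WT cells, 1 of 10 splits of the 6 libraries, the real one, gave 680 genes and the highest other gave 1. For genotype under vehicle it was 1 of 10, with 1817 genes and 0 for the highest other by edgeR. With 10 splits a share under 0.05 cannot be reached. Each other split also put libraries of unlike treatment or genotype in the same group, which widens the spread. Few calls in those splits were thus set in advance, and no conclusion is drawn from them.

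Other genes whose inhibitor effect differed between genotypes in the main fit are given as interaction log2 values. Of the 40 interaction calls, 0 held by edgeR without R183W vehicle library 2 or 3, though all 40 kept their sign there. A positive value means a more positive inhibitor effect in R183W than in WT cells, not a higher level there. Positive were SLFN5 2.11, FN1 2.01, TMEM158 1.70, CDKAL1 1.52, JAG1 1.41, LIMA1 1.32, CYP1B1 1.31, TSC22D1 1.29, SAT1 1.27 and FTL 0.78. Negative were COL1A1 -1.02, FANCD2 -1.10, POLA2 -1.42, CHAF1A -1.47, PKMYT1 -1.56 and MCM3 -1.59. So were MCM7 -1.67, E2F1 -1.68, CDC6 -1.79, RAPGEF3 -1.93, SLC48A1 -2.05 and PLAT -2.30. List medians for the interaction were -1.18 for DNA replication and S phase, -0.94 for homologous recombination and Fanconi repair, -0.24 for mitosis, -0.23 for YAP/TEAD targets, -0.25 for ATF4 and amino acid response, -0.28 for heat shock response, 0.24 for MHC class I presentation and 0.66 for NRF2 targets. With an estimated correlation the calls for mitosis, YAP/TEAD targets, heat shock response and MHC class I presentation were lost (adjusted p = 0.174, 0.137, 0.161 and 0.141).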

How the results depend on the processing

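The GC correction, leaving out libraries for lists and overlaps, and every alternative for the overlap in WT cells, were chosen only after the results were seen. Genes named regardless of their result were then also limited to KAT6A, PPP2R1A, CDKN1A and CDKN1C where they did not pass. Overlap counts with no filter, the stricter filter, only the groups compared and GC correction were computed once and then left out, because they were not among the alternatives fixed beforehand. The cause of the differences below was not tested.

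For WM1119 in R183W cells, genes higher numbered 435 by DESeq2, 455 with no filter, 1177 with only the groups compared and 145 at 2-fold or more, against 278. Genes lower numbered 655 with no filter, 1229 with only the groups compared and 232 at 2-fold, against 371. Leaving out a library gave 44 (R183W WM1119 2) to 686 (WT WM1119 3) higher and 74 (R183W WM1119 2) to 914 (WT WM1119 3) lower.

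For WM1119 in WT cells, genes higher numbered 582 by DESeq2, 678 with no filter, 47 with only the groups compared and 125 at 2-fold, against 326. Genes lower numbered 533, 609, 92 and 184 in the same order, against 354. With a library left out there were 83 (WT vehicle 3) to 803 (WT WM1119 1) higher and 160 (WT WM1119 2) to 589 (WT WM1119 1) lower.

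For R183W against WT under vehicle, genes higher numbered 1509 with only the groups compared and 437 at 2-fold, against 954, and genes lower 1420 and 385, against 863. Leaving out a library gave 506 (WT vehicle 3) to 1655 (WT WM1119 3) higher and 433 (R183W vehicle 1) to 1496 (WT WM1119 3) lower. Under WM1119, genes higher numbered 164 with only the groups compared and 382 at 2-fold, against 649. Genes lower numbered 942 with no filter, 155 with only the groups compared and 338 at 2-fold, against 548. With a library left out there were 211 (R183W WM1119 1) to 1381 (WT WM1119 3) higher and 175 (R183W WM1119 1) to 1514 (WT WM1119 3) lower.

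For the interaction, DESeq2 gave 62 higher and 107 lower and no filter 60 and 131, against 13 and 27. Leaving out a library gave 0 (R183W vehicle 2, by edgeR, with 1076 genes at an unadjusted p under 0.05) to 62 (WT WM1119 3) higher and 0 to 130 lower for the same libraries.

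Genes higher with WM1119 in both genotypes numbered 144 by DESeq2, against 91. Leaving out a library gave 25 (R183W WM1119 2) to 155 (WT WM1119 1) higher in both and 50 (R183W WM1119 1) to 227 (WT WM1119 3) lower in both. Genes higher in R183W cells and lower with WM1119 ran from 21 (R183W WM1119 2) to 228 (WT WM1119 3), and the reverse from 15 (R183W WM1119 1) to 130 (WT WM1119 3).

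In WT cells, genes higher in R183W cells that rose with WM1119 numbered 155 by DESeq2, against 91, and those lower that fell 156, against 95. They ran from 20 (WT vehicle 3) to 228 (WT WM1119 1) and from 39 (WT vehicle 2) to 154 (WT WM1119 1) over libraries left out.

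The replicate numbers did not pair libraries, and only 2 of 11 libraries correlated best with their own number. With the number as a block, genes higher and lower numbered 99 and 162 for WM1119 in R183W cells, 111 and 176 in WT cells, 627 and 562 for genotype under vehicle and 366 and 312 under WM1119. The block left 0 and 0 genes for the interaction by edgeR, with 1023 at an unadjusted p under 0.05. Overlaps under the block were 28 higher and 61 lower in both genotypes, 41 and 29 for the genotype-dependent genes in R183W cells, and 32 and 46 in WT cells. The block kept 264 of 434 named calls and 51 of 53 list calls, the others being MHC class I presentation for WM1119 in R183W cells (adjusted p = 0.0505) and heat shock response for the interaction (0.0678).

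With an estimated correlation 10, 2, 5, 4 and 4 lists passed for WM1119 in R183W cells, in WT cells, genotype under vehicle, under WM1119 and the interaction, against 16, 11, 7, 11 and 8. With fry 25, 19 and 21 passed in the first 3. Fits that left out a library gave 13 to 17, 9 to 14, 7 to 10, 9 to 11 and 6 to 10 lists. Of 53 list calls 25 held with an estimated correlation, 51 with fry and 52 after GC correction, all but MHC class I presentation for WM1119 in R183W cells.

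Of 434 named calls, DESeq2 kept 427 of the 428 with a value, GC correction 398 and limma-voom 397, and leaving out a library kept 248 (R183W WM1119 2) to 427 (WT WM1119 3). A sign turned in 3 results that had not passed. Without R183W vehicle 3, KAT6A was -0.01 and CDKN1C 0.06 for WM1119 in R183W cells, while the other ends of their ranges, without R183W vehicle 1, were 0.18 and -0.15. PPP2R1A was -0.07 for genotype under WM1119 without R183W WM1119 1 and 0.25 without R183W WM1119 2.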

Other observations

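The nuclear transcripts NEAT1 and MALAT1 and the genes below were chosen after their values were seen, and no explanation was tested. NEAT1 changed by 1.09 (SE 0.15, edgeR adjusted p = 0.000874) with WM1119 in R183W cells and by 0.56 (SE 0.13, 0.0285) in WT cells. MALAT1 changed by 0.80 (SE 0.14, edgeR adjusted p = 0.00606) in R183W cells and -0.07 (SE 0.13, 0.801) in WT cells, and its interaction did not pass (0.87, SE 0.19, 0.102). Both were lower in R183W than in WT cells under vehicle, MALAT1 by -0.68 (SE 0.13, edgeR adjusted p = 0.00383) and NEAT1 by -0.43 (SE 0.13, 0.0466).

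RPL28, a ribosomal protein gene, rose with WM1119 from 68.6 ± 21.6 to 309 ± 63.7 CPM in WT cells (log2 2.18, SE 0.26, edgeR adjusted p = 0.000522). In R183W cells it rose from 66 ± 22.3 to 234 ± 24.6 CPM (1.82, SE 0.28, 0.00242). The ribosomal protein list, which does not hold RPL28, did not rise with it. Its medians were -0.202 in WT and -0.085 in R183W cells (camera adjusted p = 0.0661 and 0.151), with 0 of 37 called in either. NDUFV1, of respiratory complex I, changed by 1.68 (SE 0.21, edgeR adjusted p = 0.00061) in WT cells and 1.13 (SE 0.22, 0.0105) in R183W cells, where the call was lost without R183W vehicle library 2 (0.0588) or 3 (0.0581) or R183W WM1119 library 1 (0.124) or 2 (0.0788). The nuclear oxidative phosphorylation list, which holds NDUFV1, had medians of -0.083 in WT and -0.009 in R183W cells. It did not pass in either (camera adjusted p = 0.553 and 0.488). Of 11 replication-dependent histone genes tested, 2 rose in R183W cells. Adjusted over the list alone 4 were higher and 3 lower, and the histone list did not pass (camera adjusted p = 0.181). H2BC12 went from 15.3 ± 0.727 to 57.4 ± 1.68 CPM and H2AC6 from 6.11 ± 0.434 to 20.9 ± 1.73 CPM.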
